A study of Mus musculus with 9 samples.

How the data were processed

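RNA was sequenced from sorted LT-HSCs of young and middle-aged C57BL/6 mice after 18 h of culture, in 9 libraries of 3 groups with 3 libraries each. The labels call the molecule polyadenylated RNA and each replicate an independent pool of mice. The deposited table holds whole-number counts per Ensembl gene, which the authors made with tools that, per the submitters' processing notes, included Bowtie2 2.2.0, RSEM 1.2.12, SAMtools 0.1.18 and edgeR 3.5.3, with GRCm38 and mm10 named as builds. The role and order of these tools, the annotation release and the strand setting are not given in the sources used here. RSEM estimates counts that need not be whole, so the deposited counts may be rounded estimates, and reads shared between near-identical genes may have been divided between them. Without a known strand setting, reads of overlapping genes on opposite strands cannot be told apart.

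The table lists 38924 genes, of which 18015 had no count in any library. Library totals ran from 5578061 to 10776358 counts. Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, which matched 96.6% of identifiers; 1317 had no symbol there. Replicates were compared by a chi-square test of their counts, and no pair of the same group differed by as little as sampling noise, so all 9 libraries were kept as separate samples.

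Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 13393 genes holding 99.9% of counts. Libraries were scaled by TMM, and edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with a mean per group to all 9 libraries, so that the 3 groups shared an estimate of the spread. The biological coefficient of variation was 0.312. The 3 pairs of groups were compared by edgeR's quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Exact permutation of 3 libraries against 3 cannot give a p under 0.1, so single values were tested in the model alone. Levels are CPM after TMM scaling. The spread between libraries of a group is what these p-values measure. The labels do not say whether control and IGF1 libraries of the same replicate number share a pool, and the fit took them as unpaired.

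Gene lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the 28 lists that had at least 5 measured members, of 29 written. Where a gene list is described, members past the threshold are counted over all genes tested and adjusted over the list alone. Intervals of count ratios are exact, at 95%, and cover counting error only; a group at 0 counts was given a floor of 3 counts over the group.

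Genes were named by a rule: for each comparison and direction, among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, the 8 with the smallest adjusted p and then the 4 with the largest change. Where fewer than 5 passed, the genes with the smallest unadjusted p filled the places and are named as not passing. Up to 4 members of each described list were added, and Igf1, Igf1r, Insr and Irs2 always. Predicted genes and pseudogenes were counted and not named, so Rpl27-ps3 lies outside the rule.

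The covariance of the age and IGF1 effects was set beside 100 simulations of unchanged groups, because both effects use the same middle-aged control libraries. The gene test was tested on simulated data with 200 planted genes in each of 5 runs. Alternatives were DESeq2's size factors, total library size, no filter, a stricter filter of 10 counts in 3 libraries, the DESeq2 1.42.0 Wald test with its own independent filtering on genes with any count, limma-voom with quality weights, the replicate number as a block, a fit of the 2 groups alone, an estimated correlation in camera, and each library left out in turn. Chosen after the data were seen were the log2 CPM of Gm42418 as a covariate, a fit without ribosomal RNA genes, the DESeq2 Wald test on the genes filterByExpr kept and without independent filtering, the covariance over genes of 5 CPM or more, and the covariance with the control libraries split between the 2 effects. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.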

Results

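Long-term haematopoietic stem cells (LT-HSCs), the rare bone marrow cells that sustain blood formation over the long term, were profiled by RNA sequencing from C57BL/6 mice. Sorted cells were kept for 18 h in serum-free medium with stem cell factor at 100 ng/ml and thrombopoietin at 50 ng/ml, 2 cytokines that support LT-HSCs in culture. The 9 libraries fell into 3 groups of 3: young cells with vehicle, middle-aged cells with vehicle, and middle-aged cells with insulin-like growth factor 1 (IGF1), a peptide hormone that signals through PI3K, AKT and mTOR, at 100 ng/ml. Young cells with IGF1 were not analysed here, so the effect of IGF1 was measured in middle-aged cells alone. Each replicate was a separate pool of mice per the labels. The libraries held 5578061 to 10776358 counts, and 13393 genes had enough counts to be tested.

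The first comparison set middle-aged against young control cells and addressed what age alone changed. The 3 genes with the smallest adjusted p, Selp, Bmpr1a and Aldh1a1, rose with age. Selp, which encodes P-selectin, an adhesion receptor of platelets and endothelium, rose 9.80-fold, from 6.78 ± 2.34 CPM (SD, n = 3) to 66.0 ± 6.37 CPM (SD, n = 3). Bmpr1a, a type I receptor for bone morphogenetic proteins, rose 19.5-fold, from 2.00 ± 0.787 to 38.95 ± 14.1 CPM (SD, n = 3 each), and Aldh1a1, a retinaldehyde dehydrogenase, rose 5.55-fold, from 22.2 ± 8.15 to 123 ± 16.1 CPM (SD, n = 3 each). Hmga2, a chromatin protein that promotes self-renewal of young stem cells, fell 3.39-fold, from 93.0 ± 12.2 to 27.5 ± 7.53 CPM (SD, n = 3 each).

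In edgeR's quasi-likelihood test, 60 of the 13393 genes passed an adjusted p of 0.05, of which 52 were higher and 8 lower in middle-aged cells. An unadjusted p under 0.05 was found for 1182 genes, where chance gives 669.7, and the groups did not overlap in 12.9% of genes, where chance gives 10%. Without young replicate 1 the count was 33 and without middle-aged control replicate 2 it was 37; it was 263 without a filter on low counts, 230 with DESeq2 on 20883 genes, which leaves out that filter too, and 231 with DESeq2 on the genes edgeR kept and without its own filter, a setting added after the data were seen.

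The adjusted p from edgeR was 2.01e-06 for Selp (log2 fold change 3.29, SE 0.24), 9.77e-06 for Bmpr1a (4.29, SE 0.37), 4.02e-05 for Aldh1a1 (2.47, SE 0.24) and 0.00248 for Hmga2 (−1.76, SE 0.26). In GRCm38 with the GENCODE M21 annotation, Selp (ENSMUSG00000026580) lies on chromosome 1 from 164115264 to 164150026, Bmpr1a (ENSMUSG00000021796) on chromosome 14 from 34410734 to 34503341, Aldh1a1 (ENSMUSG00000053279) on chromosome 19 from 20492715 to 20643465 and Hmga2 (ENSMUSG00000056758) on chromosome 10 from 120361275 to 120476469. Each value is a count over the whole gene. Selp and Hmga2 each overlap non-coding genes on the opposite strand, whose reads cannot be told apart where the strand setting of the counting is not known.

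Other genes that rose with age had varied functions. Wwtr1, which encodes the Hippo pathway coactivator TAZ, rose 14.2-fold, and the membrane protein gene Tm4sf1 rose 11.4-fold. Adgrg2, an adhesion G protein-coupled receptor, rose 10.1-fold, and Ptprk, a receptor tyrosine phosphatase, rose 9.58-fold. The microtubule-associated protein gene Map1b rose 8.79-fold, the Wnt modulator gene Sfrp1 8.11-fold, Tmem47 6.43-fold, the clusterin gene Clu 5.50-fold and the leukocyte tetraspanin gene Cd53 3.20-fold. Adjusted p ran from 0.000101 for Map1b and Wwtr1 to 0.00275 for Sfrp1 in edgeR, and in all of these genes every middle-aged library lay above every young library.

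Among the genes that fell, Emilin2, an extracellular matrix glycoprotein gene, went from 108 ± 18.7 to 38.1 ± 10.3 CPM (SD, n = 3 each) and Runx3, a transcription factor gene of the Runt family, from 199.6 ± 38.98 to 94.6 ± 6.22 CPM (SD, n = 3 each). Ndrg2 fell 2.95-fold, Ncf1, a subunit gene of the phagocyte NADPH oxidase, 5.32-fold, and the leukocyte tetraspanin gene Cd37 2.46-fold. Their adjusted p in edgeR were 0.00291 for Emilin2, 0.00783 for Runx3 and Ndrg2, 0.0162 for Ncf1 and 0.0358 for Cd37. The ribosomal protein pseudogene Rpl27-ps3, described with the IGF1 comparison, also fell. Emilin2, Runx3, Ncf1, Cd37, Tmem47, Tet3, Cd27 and Pfkp overlap genes on the opposite strand, and Rpl13a overlaps one on its own strand. The calls of Ndrg2 and Runx3 were lost without young replicate 1 (adjusted p = 0.0625 for each in edgeR), that of Runx3 also without middle-aged control replicate 2 (0.0659), that of Ncf1 without young replicate 1 or 2 or middle-aged control replicate 1 or 2 (0.0516 to 0.0918), and that of Cd37 without young replicate 1 or 3 or middle-aged control replicate 2 or 3 (0.115 to 0.166).

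**Figure D1:**
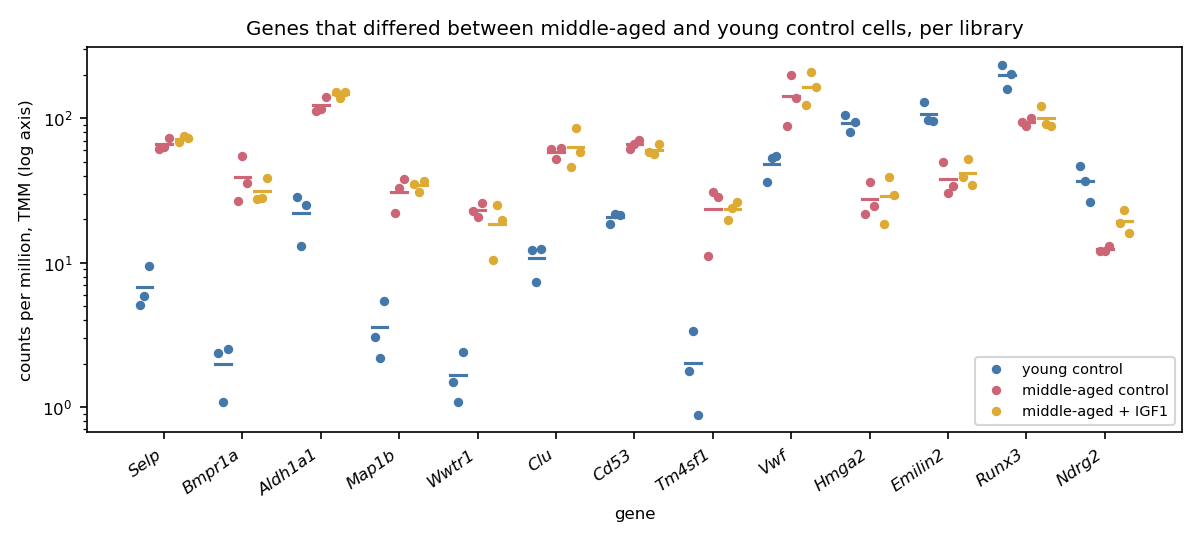
CPM after TMM scaling, on a log axis, for 13 genes that passed the test between middle-aged and young control cells. Points are the 3 libraries of each group and lines are group means; Selp sits at a mean of 6.78 CPM in young, 66.0 CPM in middle-aged control and 72.3 CPM in middle-aged IGF1 libraries, and Hmga2 at 93.0, 27.5 and 29.2 CPM.

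The gene lists, written before the data were examined, placed these genes in groups. Of the 39 measured genes of the list of genes known to be higher in old HSCs, 38 had a positive log2 fold change and 20 rose over all genes tested, or 30 adjusted over the list alone. The list's median log2 fold change was 1.72, also with Mt2, at 0 counts in young libraries, set at its bound (camera adjusted p = 3.61e-89; adjusted p = 0.000305 with an estimated correlation). Its members Bmpr1a, Wwtr1 and Tm4sf1 are given above; Osmr, the oncostatin M receptor gene, had 152 counts in middle-aged and 5 in young control libraries, a ratio of 30.9 with a 95% counting interval of 12.9 to 96.4. The call of Osmr was lost without young replicate 1 (adjusted p = 0.0625 in edgeR) and without middle-aged control replicate 2 (0.0643).

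Megakaryocyte and platelet genes rose as a list, with a median of 0.45 (camera adjusted p = 1.76e-11; adjusted p = 0.0485 with an estimated correlation). Of 28 measured members, 4 rose over all genes and 8 adjusted over the list alone. Besides Selp these were Vwf, the von Willebrand factor gene (47.9 ± 10.2 to 142 ± 55.4 CPM; SD, n = 3 each), Slc14a1, a urea transporter gene (2.16-fold), and Mmrn1, the multimerin 1 gene (2.03-fold). The list shares 5 measured members with the HSC ageing list. The other 23 had a median of 0.42, with an unadjusted camera p of 1.88e-05 at the preset correlation and 0.0787 with an estimated one, so without the shared members the rise rests on the preset correlation. Vwf lost its call without young replicate 1 (adjusted p = 0.0625 in edgeR) and without middle-aged control replicate 2 (0.0607), Slc14a1 without each library but middle-aged control replicate 3 (0.0569 to 0.118), and Mmrn1 without each but middle-aged control replicate 1 (0.0692 to 0.159).

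Interferon response genes had a median of 0.33, with 43 of 51 measured members positive (camera adjusted p = 1.66e-06; adjusted p = 0.0485 with an estimated correlation). A single member, the guanylate-binding protein gene Gbp4, passed over all genes, and 3 passed adjusted over the list alone. Gbp4 had 157 counts in middle-aged and 3 in young control libraries, a ratio of 53.1 with a 95% counting interval of 17.9 to 260.4. It overlaps its paralogs Gbp8 and Gbp9 on the same strand, and its call was lost without young replicate 1 or 3 or middle-aged control replicate 1 or 3 (adjusted p = 0.0745 to 0.134 in edgeR). The antiviral gene Oas3 had 8.53 ± 2.01 and 20.8 ± 4.61 CPM (SD, n = 3 each), Iigp1 had 13.1 ± 1.91 and 30.9 ± 12.2 CPM, and Gbp3 had 8.58 ± 2.65 and 17.6 ± 4.94 CPM, with adjusted p of 0.0743, 0.0872 and 0.216 in edgeR, none of which passed. Oas3 and Iigp1 did pass without a filter on low counts and with DESeq2 on either set of genes (adjusted p = 0.00322 to 0.00994). Oas3 also passed with the log2 CPM of the ribosomal RNA signal Gm42418 as a covariate (0.0392) and Iigp1 also without middle-aged control replicate 1 (0.021).

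Chromatin and DNA methylation regulators fell as a list, with a median of −0.21 and 29 of 43 measured members negative (camera adjusted p = 0.0033; adjusted p = 0.0485 with an estimated correlation). Hmga2 was the 1 member that passed, over all genes and adjusted over the list alone. Tet3, a methylcytosine dioxygenase gene, had 88.5 ± 11.2 and 60.7 ± 7.90 CPM, and Dnmt3b, a DNA methyltransferase gene, 170 ± 13.8 and 119 ± 20.1 CPM (SD, n = 3 each), with adjusted p of 0.28 and 0.361 in edgeR.

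The remaining lists passed camera's preset correlation of 0.01 but not an estimated one. Stem cell identity and quiescence genes had a median of 0.15, with 31 of 40 members positive (camera adjusted p = 0.0108; adjusted p = 0.0769 with an estimated correlation). Mycn rose 1.76-fold (adjusted p = 0.0417 in edgeR); the call was lost whichever of the 6 libraries was left out (0.0717 to 0.149). Mecom, a transcription factor gene of HSC self-renewal that overlaps other genes on both strands, had 66.7 ± 11.03 and 113 ± 20.5 CPM (SD, n = 3 each; adjusted p = 0.137 in edgeR) and passed without a filter on low counts and with DESeq2 on either set of genes (0.0165 to 0.0312). Endothelial and stromal markers had a median of 0.57 over 10 measured members (camera adjusted p = 0.00938; adjusted p = 0.0943 with an estimated correlation). Of these the collagen gene Col1a2 rose 6.19-fold from 3.24 ± 0.849 CPM (SD, n = 3; adjusted p = 0.00153 in edgeR), while the VEGF receptor gene Flt1 had 4.56 ± 1.30 and 10.7 ± 7.74 CPM (adjusted p = 0.483). Immediate early genes had a median of 0.34 (camera adjusted p = 0.0345; adjusted p = 0.488 with an estimated correlation), with the AP-1 gene Fosl1 at 19.4 ± 5.05 and 34.0 ± 6.08 CPM (SD, n = 3 each; adjusted p = 0.197 in edgeR, and 0.036 with the Gm42418 covariate). That list was not past the threshold without young replicate 2 (adjusted p = 0.115) or middle-aged control replicate 1 (0.322).

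The other lists that fell had medians from −0.48 to −0.12 and passed the preset correlation alone. Members of a list can move together, with an estimated correlation of 0.66 for ribosomal protein genes and 0.51 for histone genes. Counts of members are thus not counts of separate observations. Cytosolic ribosomal protein genes had a median of −0.20, with 71 of 74 members negative and none passing alone (camera adjusted p = 3.48e-07; adjusted p = 0.667 with an estimated correlation); Rpl18a had 960.0 ± 159 and 703 ± 34.0 CPM and Rpl13a 554 ± 113 and 423 ± 29.3 CPM (SD, n = 3 each). Nuclear-encoded oxidative phosphorylation genes had a median of −0.13 (camera adjusted p = 0.00591; adjusted p = 0.667 with an estimated correlation), Cox6a1 being at 202 ± 39.1 and 156 ± 20.6 CPM. G2/M and mitosis genes had a median of −0.14, with 46 of 53 members negative (camera adjusted p = 0.000461; adjusted p = 0.453 with an estimated correlation); the mitotic kinesin gene Kif2c had 25.6 ± 2.84 and 14.2 ± 3.97 CPM and the phosphatase gene Cdc25c 14.2 ± 2.73 and 5.95 ± 3.83 CPM. Lymphoid markers had a median of −0.48 over 13 measured members (camera adjusted p = 0.0339; adjusted p = 0.453 with an estimated correlation), with the TNF receptor family gene Cd27 at 95.4 ± 11.3 and 44.4 ± 16.6 CPM and Gimap6 at 27.6 ± 8.11 and 17.7 ± 2.01 CPM. Antioxidant genes had a median of −0.12 (camera adjusted p = 0.0345; adjusted p = 0.453 with an estimated correlation), with Gpx1 at 455 ± 70.3 and 331 ± 24.6 CPM. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, had a median of −0.24 (camera adjusted p = 0.0212; adjusted p = 0.667 with an estimated correlation), with Hist1h1c at 33.7 ± 19.01 and 15.3 ± 1.63 CPM. None of the 9 genes named for these 6 lists passed in edgeR. Under other settings Cd27 passed without a filter on low counts, with DESeq2 on either set of genes, with limma-voom and with the replicate number as a block (adjusted p = 8.56e-05 to 0.0219). Cd27 also passed without middle-aged control replicate 2 (0.0286), and Hist1h1c without a filter (0.00457) and without young replicate 2 (0.015). Myeloid, granulocyte and mast cell markers did not pass as a list (camera adjusted p = 0.868).

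The counts of Gm42418, an annotated gene that covers ribosomal RNA sequence, made up 4.57 ± 1.77% of young and 3.00 ± 0.646% of middle-aged control libraries (SD, n = 3 each). At the preset correlation 13 lists passed with age, 6 higher and 7 lower. With the log2 CPM of Gm42418 as a covariate, an alternative added after the data were seen, 14 passed, 12 higher and 2 lower. The histone list then turned to a median of 0.44 (camera adjusted p = 0.00524), and the ribosomal protein and oxidative phosphorylation lists had medians of −0.02 and 0.005 and were no longer past the threshold (adjusted p = 0.434 and 0.987). The antioxidant list also lost its call, with a median of −0.09 (0.389). So did the lymphoid list (0.0549), whose median grew in size to −0.56 while the median SE of a member rose from 0.39 to 0.49. The histone list was also lost without young replicate 1 (adjusted p = 0.124), young replicate 3 (0.969) or middle-aged control replicate 3 (0.717). The oxidative phosphorylation list was lost without young replicate 1 (0.512) or middle-aged control replicate 3 (0.297). The lymphoid list was lost without young replicate 2 (0.104) or middle-aged control replicate 1 (0.224) or 3 (0.262). The antioxidant list was lost without young replicate 3 (0.167) or middle-aged control replicate 2 (0.0577) or 3 (0.087).

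The IGF1 pathway genes named by the rule did not pass the test with age. The receptor gene Igf1r (ENSMUSG00000005533, chromosome 7, 67952827 to 68233668) had 32.5 ± 7.11 CPM in young and 33.9 ± 3.96 CPM in middle-aged control cells (SD, n = 3 each; log2 fold change 0.06, 95% interval −0.40 to 0.53), and the insulin receptor gene Insr had 39.2 ± 11.4 and 48.0 ± 12.6 CPM (SD, n = 3 each; adjusted p = 0.823 in edgeR). The adaptor gene Irs2 had 13.2 ± 20.6 and 3.14 ± 0.767 CPM (adjusted p = 0.536 in edgeR, and 0.00356 without a filter on low counts), with young replicate 3 at 36.9 CPM and the other young libraries at 1.19 and 1.39 CPM. Igf1 itself had 0 to 8 counts per library. The list of IGF1, PI3K, AKT and mTOR pathway components did not pass (camera adjusted p = 0.386; median 0.03, mean −0.13 and test direction down), nor did glycolysis (0.396) or cholesterol synthesis (0.0816), although the phosphofructokinase gene Pfkp (1.76-fold, adjusted p = 0.0284) and the desaturase gene Scd1 (2.50-fold, adjusted p = 0.0433) rose in edgeR. The calls of Pfkp and Scd1 were lost without each library but middle-aged control replicate 1 (0.0799 to 0.108 and 0.0625 to 0.209). Among other settings, limma-voom with quality weights ended the calls of Ndrg2, Ncf1, Osmr and Gbp4, the Gm42418 covariate those of Cd37, Vwf, Mmrn1, Gbp4 and Scd1, and a fit of the 2 groups alone those of Cd37, Osmr, Mycn, Pfkp and Scd1, with adjusted p from 0.0511 to 0.279. All of these genes kept their direction. With the covariate the log2 fold change went from 1.56 (SE 0.27) to 1.43 (SE 0.32) for Vwf, from 1.32 (SE 0.28) to 1.14 (SE 0.34) for Scd1, from 1.02 (SE 0.21) to 0.81 (SE 0.23) for Mmrn1 and from −1.30 (SE 0.27) to −0.95 (SE 0.26) for Cd37. In the fit of the 2 groups it was −1.29 for Cd37, 0.82 for Mycn and Pfkp and 1.33 for Scd1, against −1.30, 0.81, 0.82 and 1.32, with a larger SE for each. With limma-voom it went from −1.56 to −1.36 for Ndrg2 and from −2.41 to −2.17 for Ncf1, also with a larger SE. For Osmr it was 4.49 with limma-voom and 4.83 in the fit of the 2 groups, against 4.84. For Gbp4 it was 5.92 with limma-voom and 5.35 with the covariate, against 5.51. The SE was larger in each of these fits.

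**Figure D2:**
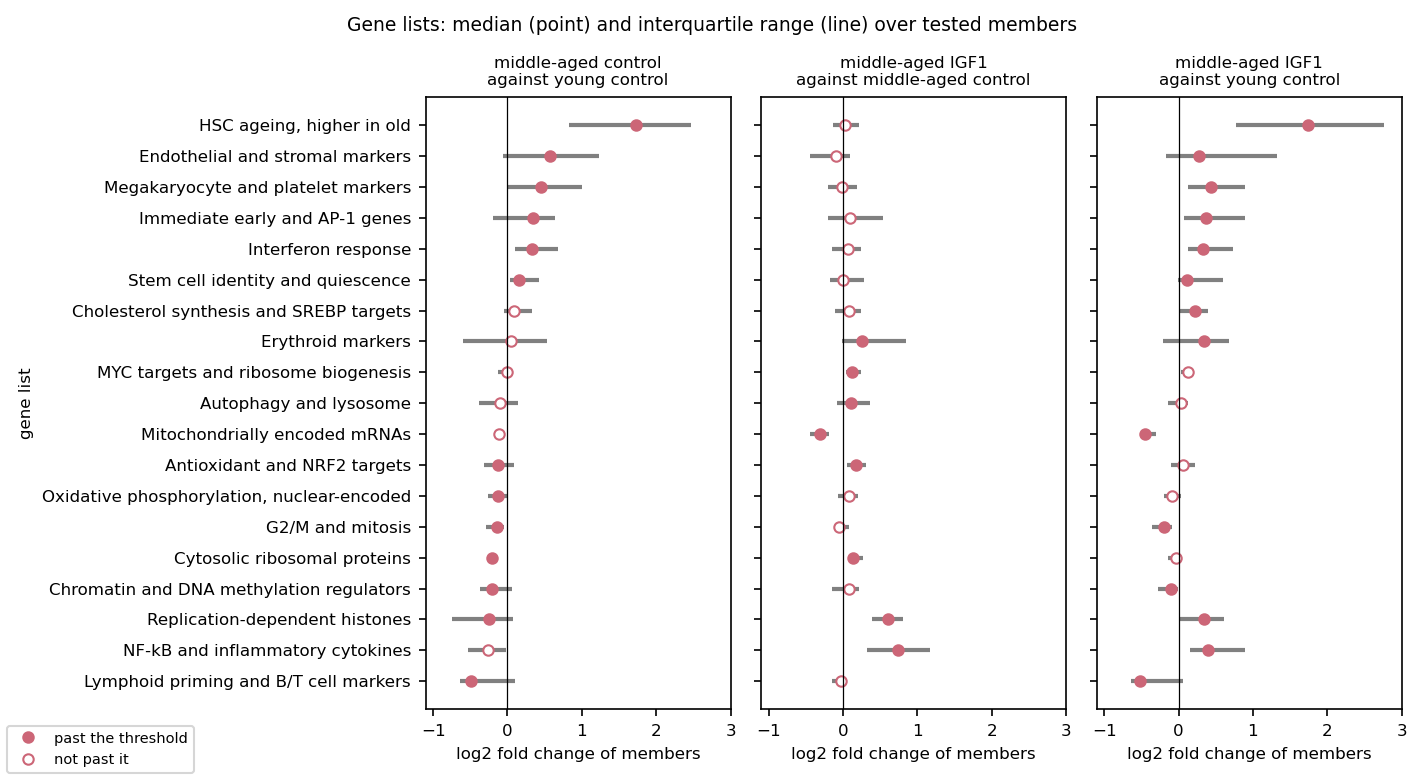
Median (point) and interquartile range (line) of the members' log2 fold changes for each gene list that passed in any of the 3 comparisons. Filled points passed camera with a preset correlation of 0.01; the HSC ageing list sits at 1.72 with age, 0.03 with IGF1 and 1.74 for IGF1-treated middle-aged against young cells.

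The second comparison set middle-aged cells with IGF1 against middle-aged cells with vehicle and addressed what IGF1 changed within 18 h. In edgeR 1 gene could be told from the spread between libraries, and 8 of the 28 gene lists passed camera at the preset correlation of 0.01 but none with an estimated one (lowest adjusted p = 0.547). Replication-dependent histone genes had a median log2 fold change of 0.60, with 36 of 39 measured members higher. The median turned to −0.35 with the ribosomal RNA signal of Gm42418 as a covariate, an alternative added after the data were seen. The Gm42418 share did not overlap between these groups, so that fit carries a slope within groups across the gap. NF-kB and inflammatory genes had a median of 0.75, with 24 of 25 higher, which was 0.18 without IGF1 replicate 1. Mitochondrially encoded mRNAs were lower in all 13 members, with a median of −0.31. These members moved together, with an estimated correlation of 0.72, so they are not 13 separate observations. Genes known to be higher in old HSCs, which rose with age, had a median of 0.03.

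In edgeR, 1 of 13393 genes passed, the pseudogene Rpl27-ps3, which lies outside the rule for named genes and was chosen after its value was seen. An unadjusted p under 0.05 was found for 500 genes, where chance gives 669.7, and the groups did not overlap in 7.81% of genes, where chance gives 10%. In simulated libraries, changes were planted in the IGF1 group and tested against the young group, also 3 libraries against 3. A 2-fold change was called in 40.0% of the planted genes and a 1.5-fold change in 4.48%. The planted genes, 200 per run, all had at least 5 CPM, so these shares do not cover lower levels or a response of few genes. The edgeR count was 0 with total library size in place of TMM, with a stricter filter, with the 2 groups fitted alone and with the Gm42418 covariate (481 to 643 genes at an unadjusted p under 0.05), 2 with DESeq2, both on 20883 genes and on the genes edgeR kept, and 54 without a filter on low counts.

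Rpl27-ps3 (ENSMUSG00000073640), a processed copy of the ribosomal protein gene Rpl27 on chromosome 18 from 6332632 to 6333042, had 109 ± 13.7 CPM in young control, 18.8 ± 14.5 CPM in middle-aged control and 117 ± 44.5 CPM in middle-aged IGF1 cells (SD, n = 3 each). It fell 5.79-fold with age (adjusted p = 0.00311 in edgeR) and rose 6.20-fold with IGF1 (adjusted p = 0.0484). Reads of a pseudogene and its parent gene can be divided wrongly between them, so its level is uncertain. The IGF1 call was lost without middle-aged control replicate 1 (adjusted p = 0.167) or 2 (0.757) and without IGF1 replicate 1 (0.103), 2 (0.618) or 3 (0.0868). It was also lost with total library size (0.0705), a stricter filter (0.0506), the 2 groups alone (0.0557) and the Gm42418 covariate (0.35). The log2 fold change was 2.63 (SE 0.39) and stayed at 2.63 to 2.66 in the first 3 of these; with the covariate it was 2.90 with a larger SE of 0.59.

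The next 10 genes by unadjusted p under the naming rule did not pass. Hist1h2ak, Lars2, Sidt2 and Dcaf5 were 2.72-fold, 1.69-fold, 1.92-fold and 1.70-fold higher with IGF1, and Mpc1, Trappc6b, Fam76b and Skp2 were 2.26-fold, 2.01-fold, 1.68-fold and 1.58-fold lower, all with an adjusted p of 0.999 in edgeR. Zfp467 was 5.94-fold higher with 51.4 CPM in IGF1 replicate 2 against 8.06 and 5.67 CPM in the other IGF1 libraries, and Lyplal1 was 4.18-fold lower with 24.8 CPM in control replicate 2 against 5.29 and 5.12 CPM in the other control libraries. Without a filter on low counts Hist1h2ak, Zfp467, Lars2 and Trappc6b passed (adjusted p = 3.46e-06 to 0.0456). Part of Lars2 resembles ribosomal RNA, and Mpc1 and Skp2 overlap genes on the opposite strand. Igf1r had 33.9 ± 3.96 and 37.4 ± 3.79 CPM, Insr 48.0 ± 12.6 and 44.5 ± 2.39 CPM and Irs2 3.14 ± 0.767 and 5.96 ± 3.52 CPM (SD, n = 3 each), none of which passed.

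Of the 8 lists that passed camera, 7 were higher and 1 lower with IGF1; with the Gm42418 covariate 8 also passed, but 2 higher and 6 lower. Without IGF1 replicate 1 the count was 5, 3 higher and 2 lower. None passed with an estimated correlation. Members of the ribosomal protein and MYC lists also moved together, with estimated correlations of 0.67 and 0.35. Their counts of members are thus not counts of separate observations. Histone genes had a camera adjusted p of 1.77e-12 (adjusted p = 0.547 with an estimated correlation); no member passed over all genes and 1 passed adjusted over the list alone. Hist1h2ak had 14.5 ± 1.32 and 39.5 ± 9.56 CPM and Hist1h2bj 3.97 ± 1.40 and 10.6 ± 4.31 CPM (SD, n = 3 each). Cytosolic ribosomal protein genes had a median of 0.13, with 64 of 74 members higher (camera adjusted p = 1.1e-05; adjusted p = 0.753 with an estimated correlation); Rpl17 had 368 ± 48.1 and 526 ± 151 CPM and Rpl6 616 ± 101 and 803 ± 156 CPM. MYC targets and ribosome biogenesis genes had a median of 0.11, with 38 of 45 higher (camera adjusted p = 0.00804; adjusted p = 0.753 with an estimated correlation), the snoRNP gene Gar1 being at 44.9 ± 3.40 and 76.0 ± 19.6 CPM. Mitochondrially encoded mRNAs had a camera adjusted p of 8.64e-06 (adjusted p = 0.641 with an estimated correlation); mt-Co1 had 21115 ± 3594 and 15468 ± 3397 CPM and mt-Co3, which overlaps mt-Atp6, 2388 ± 586 and 1727 ± 307 CPM.

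NF-kB genes had a camera adjusted p of 3.28e-08 (adjusted p = 0.547 with an estimated correlation), and the shift rested on IGF1 replicate 1. In that library all 25 members lay above the control mean, by a median of 1.38, against 0.33 in replicate 2 and 0.07 in replicate 3. Bcl3, an IkB family gene, was at 50.6, 14.2 and 6.70 CPM in the 3 IGF1 libraries, Relb at 19.1, 1.46 and 1.03 CPM, and the activation marker Cd69 at 26.5, 1.07 and 2.58 CPM; Tnip1 had 15.03 ± 1.95 and 25.9 ± 11.7 CPM (SD, n = 3 each). Without a filter on low counts Bcl3, Relb and Cd69 passed in edgeR (adjusted p = 0.000284 to 0.0384). Without IGF1 replicate 1 the list had a median of 0.18 and did not pass (adjusted p = 0.361).

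Antioxidant genes had a median of 0.18 (camera adjusted p = 0.000561; adjusted p = 0.547 with an estimated correlation), with the ferritin light chain gene Ftl1 at 674 ± 69.4 and 978 ± 136 CPM and Gpx4 at 27.1 ± 3.49 and 38.9 ± 1.61 CPM (SD, n = 3 each). Autophagy and lysosome genes had a median of 0.10 (camera adjusted p = 0.0295; adjusted p = 0.641 with an estimated correlation), with the kinase gene Ulk1 at 25.8 ± 4.38 and 41.4 ± 5.15 CPM. Erythroid markers had a median of 0.25 (camera adjusted p = 0.0481; adjusted p = 0.547 with an estimated correlation), with the alpha globin copies Hba-a2 at 22.5 ± 10.8 and 44.6 ± 26.4 CPM and Hba-a1 at 12.9 ± 2.91 and 23.8 ± 9.87 CPM, which can share reads. Hba-a2 passed in edgeR without a filter on low counts (adjusted p = 0.0407). IGF1 and mTOR pathway components (median 0.10, camera adjusted p = 0.537), FOXO targets (median −0.10, 0.40), nuclear-encoded oxidative phosphorylation genes (median 0.08, 0.153) and the HSC ageing list (0.865) did not pass. The oxidative phosphorylation list did pass with total library size (0.0255), without control replicate 1 (0.0351) or 2 (0.0204) and without IGF1 replicate 3 (0.00178).

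**Figure D3:**
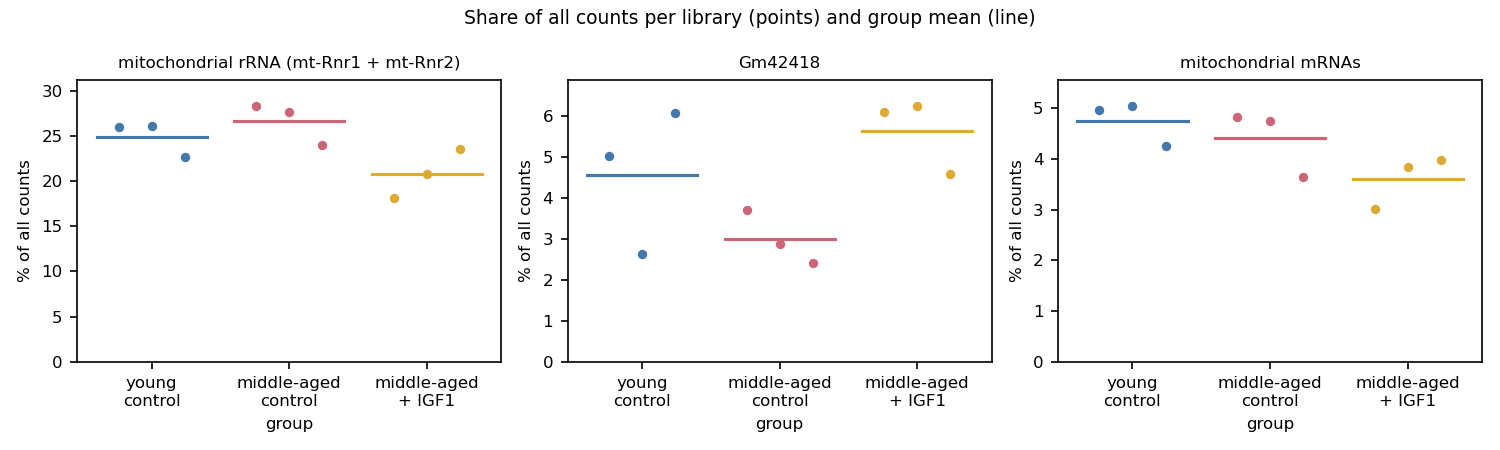
Share of all counts, in percent, taken by the mitochondrial ribosomal RNAs, by Gm42418 and by mitochondrial mRNAs. Points are libraries and lines are group means; mitochondrial ribosomal RNA sits at 26.7% in middle-aged control and 20.8% in middle-aged IGF1 libraries, and Gm42418 at 3.00% and 5.65%.

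The libraries also differed in composition. Gm42418 took 3.00 ± 0.646% of counts in middle-aged control and 5.65 ± 0.913% in IGF1 libraries, and the mitochondrial ribosomal RNAs 26.7 ± 2.35% and 20.8 ± 2.72% (SD, n = 3 each). The Gm42418 share ran from 2.42 to 3.70% in the control and from 4.60 to 6.26% in the IGF1 libraries, without overlap. The covariate fit thus carries a slope seen within groups across that gap. It cannot tell library composition from an effect of IGF1 on Gm42418 itself. With the Gm42418 covariate the histone list turned to a median of −0.35 (camera adjusted p = 0.00267) and the ribosomal protein list to −0.15 (0.0015), the MYC, autophagy and antioxidant lists were no longer past the threshold (0.0658, 0.804 and 0.571; medians −0.09, 0.02 and −0.0017), and oxidative phosphorylation genes passed with a median of −0.15 (0.0023). The ribosomal protein list was lost without control replicate 3 (adjusted p = 0.236) or IGF1 replicate 1 (0.393), and the MYC list without control replicate 2 (0.0883) or 3 (0.234) or IGF1 replicate 1 (0.999). The autophagy list was lost without control replicate 1 (0.203) or 3 (0.0648) or IGF1 replicate 2 (0.627), and the erythroid list without control replicate 1 (0.118) or 2 (0.262) or IGF1 replicate 1 (0.175) or 3 (0.0945), and also with total library size (0.0802) and a stricter filter (0.106).

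The third comparison set middle-aged cells with IGF1 against young control cells, where age and IGF1 both differed. Many of the genes named were also named for age. Selp rose 10.7-fold to 72.3 ± 3.46 CPM, Aldh1a1 6.65-fold to 148 ± 8.07 CPM and Bmpr1a 15.8-fold to 31.6 ± 6.15 CPM (SD, n = 3 each). Mt1, a metallothionein gene, rose 4.64-fold from 7.50 ± 2.65 to 34.9 ± 2.42 CPM. Cd34, a surface antigen gene of progenitors, fell 2.42-fold from 250.1 ± 28.8 to 103 ± 34.96 CPM, and Hmga2 fell 3.19-fold to 29.2 ± 10.3 CPM (SD, n = 3 each).

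In edgeR, 78 of 13393 genes passed, 68 higher and 10 lower, with 1075 at an unadjusted p under 0.05, where chance gives 669.7, and 13.4% without overlap, where chance gives 10%. The count was 36 without young replicate 1, 45 without IGF1 replicate 2 and 43 without IGF1 replicate 3; it was 269 without a filter on low counts, 224 with DESeq2 on 20883 genes and 221 with DESeq2 on the genes edgeR kept. Of the 52 genes that rose with age 43 also rose here, and of the 8 that fell 4 also fell here, while independent lists would share 0.264 and 0.00597 genes. Both comparisons used the same young libraries, which alone favour shared calls, so independence is not the value without change and the overlap is given as a count only.

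Adjusted p in edgeR was 1.17e-06 for Selp, 1.52e-05 for Aldh1a1, 1.81e-05 for Bmpr1a, 0.000414 for Mt1, 0.0041 for Hmga2 and 0.0155 for Cd34. Map1b (9.73-fold), Clu (5.94-fold), Wwtr1 (11.2-fold), Cd53 (2.94-fold), Tm4sf1 (11.4-fold), Ptprk (9.79-fold) and Adgrg2 (9.43-fold) were higher than in the same young libraries, as was Opcml, a neuronal adhesion gene (9.30-fold, adjusted p = 0.0236). Emilin2 (2.55-fold) and Runx3 (1.97-fold) were lower. Also lower were Gmfg, an actin-remodelling gene (3.03-fold), Kif21b, a kinesin gene (2.60-fold), Clec4e, the Mincle receptor gene (9.07-fold, from 10.04 ± 3.91 to 1.12 ± 0.371 CPM; SD, n = 3 each), and Rgs7bp (3.39-fold). Cd34 overlaps a gene on the opposite strand. Cd34 and Emilin2 were not past the threshold without IGF1 replicate 3 (adjusted p = 0.102 and 0.0619), Cd34 also without IGF1 replicate 1 (0.085) and Emilin2 also without young replicate 1 (0.0531); Opcml was lost without young replicate 1 or 2 or IGF1 replicate 2 or 3 (0.0714 to 0.12), and Runx3 without young replicate 1 or 3 or IGF1 replicate 2 or 3 (0.0754 to 0.12). Gmfg (0.0567 to 0.136) and Kif21b (0.0554 to 0.154) were lost without young replicate 1 or any IGF1 replicate, Clec4e without each library but young replicate 3 (0.0562 to 0.144) and Rgs7bp without each but IGF1 replicate 2 (0.0933 to 0.153). Limma-voom with quality weights ended the calls of Opcml, Gmfg, Clec4e and Oas3, and the Gm42418 covariate those of Rgs7bp and Oas3 (0.0527 to 0.0863). With the covariate the log2 fold change went from −1.76 (SE 0.37) to −1.65 (SE 0.39) for Rgs7bp and from 1.47 (SE 0.30) to 1.27 (SE 0.31) for Oas3, and with limma-voom it was 1.36 for Oas3, 2.93 for Opcml, −1.43 for Gmfg and −2.92 for Clec4e, against 1.47, 3.22, −1.60 and −3.18.

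Of the 28 lists 14 passed, 10 higher and 4 lower, and 5 of them also with an estimated correlation. With the Gm42418 covariate 13 passed, 7 higher and 6 lower. The HSC ageing list had a median of 1.74, with 18 of 39 members risen over all genes and 30 adjusted over the list alone (camera adjusted p = 3.14e-95; adjusted p = 0.000259 with an estimated correlation). Interferon response genes had a median of 0.33 (camera adjusted p = 2.13e-09; adjusted p = 0.0278 with an estimated correlation), and Oas3 rose 2.77-fold (adjusted p = 0.0302 in edgeR), a call lost without young replicate 1 or 2 or IGF1 replicate 1 or 2 (0.116 to 0.128). Megakaryocyte and platelet genes (median 0.44), stem cell identity genes (0.11) and chromatin regulators (−0.10) each had an adjusted p of 0.0457 with an estimated correlation. Igf1r, Insr and Irs2 did not pass (adjusted p = 0.937, 0.959 and 0.873 in edgeR).

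The other lists passed the preset correlation alone. Immediate early genes had a median of 0.38 (adjusted p = 0.161 with an estimated correlation), erythroid markers 0.34 (0.117), cholesterol synthesis genes 0.22 (0.153), endothelial and stromal markers 0.27 (0.161), NF-kB genes 0.40 (0.611) and histone genes 0.35 (0.719). Mitochondrially encoded mRNAs had a median of −0.46 (0.228), G2/M and mitosis genes −0.20 (0.209) and lymphoid markers −0.52 (0.235). Gm42418 took 4.57 ± 1.77% of counts in young control and 5.65 ± 0.913% in IGF1 libraries, and the mitochondrial ribosomal RNAs 24.9 ± 1.96% and 20.8 ± 2.72% (SD, n = 3 each). Without IGF1 replicate 1 the NF-kB list had a median of −0.13 (adjusted p = 0.846), the histone list 0.16 (0.208) and the cholesterol synthesis list 0.14 (0.0677). The histone list was also lost without young replicate 2 (0.832), the endothelial and stromal list likewise (0.0552), the erythroid list without young replicate 3 (0.0871) and the lymphoid list without IGF1 replicate 3 (0.0756). The Gm42418 covariate ended the calls of the histone (0.903) and endothelial and stromal (0.131) lists, whose medians fell to 0.05 and 0.07, and of the NF-kB list (0.0514), whose median stayed at 0.40. The endothelial and stromal list was also lost with total library size (0.0516) and without a filter on low counts (0.0555).

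The last comparison asked whether IGF1 moved the genes that age had moved. Among the 52 genes that rose with age, 25 were higher and 27 lower with IGF1 than with vehicle, with a median log2 fold change of −0.02. Of the 8 genes that fell with age, 7 were higher with IGF1 and none lower, with a median of 0.27. The other gene had no count in either middle-aged group. These genes were selected on the control libraries that both comparisons share, which by itself favours values towards the young level in both sets. Of the 52 genes, 28 were higher and 24 lower with total library size, 27 and 25 without IGF1 replicate 1, and 33 and 19 without middle-aged control replicate 2, with medians of 0.04, 0.03 and 0.05. They were 21 and 31 without middle-aged control replicate 1 (median −0.13) and without IGF1 replicate 2 (−0.04) or 3 (−0.09), and 20 and 32 with the Gm42418 covariate (−0.15). Of the 8, 6 were higher and 1 lower without middle-aged control replicate 1 or IGF1 replicate 1, 5 and 2 without IGF1 replicate 2, and 3 and 5 with the Gm42418 covariate, with a median of −0.09. Rpl27-ps3 was the 1 gene called in both comparisons, in opposite directions. Independent lists would share 0.000597 genes, but that value does not allow for the shared controls, whose low counts alone favour such a pair of calls. Selp, Aldh1a1 and Hmga2 had IGF1 log2 fold changes of 0.13, 0.26 and 0.09, with 95% intervals of −0.32 to 0.58, −0.20 to 0.73 and −0.46 to 0.64.

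Across genes, which are not independent replicates, the covariance of the age and IGF1 log2 fold changes was −0.125 and their Pearson correlation −0.33. Both share the middle-aged control libraries, which gives a negative value with no effect at all. In 100 simulations of unchanged groups the covariance averaged −0.127, between −0.138 and −0.116, and the correlation −0.50, between −0.53 and −0.47, so the observed covariance lay inside its simulated range and the observed correlation above its own. The simulations draw each gene on its own, so they leave out any spread that genes share. The covariance lay 0.0022 above the simulated mean, and the share of simulations at least as far from it, counting the observed value as one, was 0.673. Without 1 library this difference was −0.0245 (young replicate 1), −0.0332 (young replicate 2), −0.161, 0.0405 and −0.0561 (middle-aged control replicates 1, 2 and 3), each with a share of 0.0099, the smallest that 100 simulations give, and −0.0176 (IGF1 replicate 3; 0.0198). It was −0.00158 and −0.0116 without IGF1 replicates 1 and 2 (0.851 and 0.099) and 0.0109 without young replicate 3 (0.168). With the replicate number as a block it was −0.0108 (0.0297), without a filter −0.155 (0.0099) and with limma-voom −0.0061 (0.257). With DESeq2's size factors, total library size and the stricter filter it was 0.0028, 0.0030 and 0.0021 (0.584, 0.545 and 0.624).

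The control libraries were also split, after the data were seen, so that 1 served one effect and the other 2 the other effect. In the 6 splits the covariance ran from 0.00501 to 0.0565 and the difference from the simulated mean from 0.0088 to 0.0608, beyond the simulated range in 5 of them. In the other, with the age effect against control replicate 2 alone, the share was 0.257. The difference was positive in all 6 splits, while with shared controls its sign changed with the libraries and settings used. The simulations also draw each library on its own. They leave out any spread that control and IGF1 libraries of the same number share, which alone would favour positive values in the splits. No direction is drawn from the difference.

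**Figure D4:**
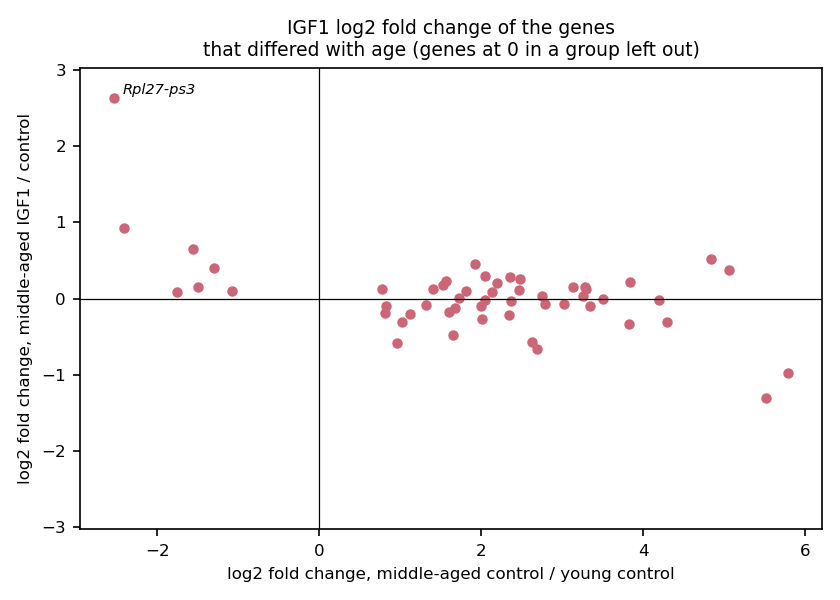
Log2 fold change with IGF1 (vertical axis) against log2 fold change with age (horizontal axis) for each gene that passed the age comparison, leaving out genes at 0 in every library of a group. Genes that rose with age spread around 0 on the vertical axis, with a median of −0.02 over all 52, or −0.15 with the Gm42418 covariate; of the 8 that fell with age, 7 were higher and none lower with IGF1, with a median of 0.27, or 3 and 5 with that covariate. Rpl27-ps3 sits apart at 2.63.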

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

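The Gm42418 covariate, the fit without ribosomal RNA genes, DESeq2 on the genes edgeR kept, the split controls and the covariance over genes of 5 CPM or more were chosen after the data were seen; the other settings were planned. Of the named genes' values under other settings, 1052 kept their direction and side of the threshold, 26 lost the call, 26 gained one and 6 changed direction; with a library left out these were 513, 84, 3 and 6. Of the gene lists' values, 265, 39, 1 and 7 did so under other settings and 194, 32, 3 and 5 with a library left out. These values include genes and lists that never passed. Of the genes past the threshold that the text reports, 16 of 28 kept direction and call in every setting for age. These were 0 of 1 for IGF1 and 12 of 21 for IGF1-treated against young cells. Of the lists past it, 4 of 13, 0 of 8 and 5 of 14 did so, with the estimated correlation among the settings. Except where stated, the cause was not tested. At this depth and number of libraries, 40.0% of genes planted at 2-fold in the simulated IGF1 group were called against the young group. The planted genes all had at least 5 CPM.

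Without a filter on low counts, where 20909 genes were tested, edgeR called 263, 54 and 269 genes for age, IGF1 and IGF1-treated against young cells, against 60, 1 and 78, all of which were also called there. Some of the added calls followed a high value in a single library, as for Relb, Cd69 and Zfp467 with IGF1 and Irs2 with age. DESeq2 on 20883 genes called 230, 2 and 224, and, without independent filtering, on the genes edgeR kept 231, 2 and 221, so that 2 choices differ between these runs; both held all of the 60, 1 and 78. For IGF1 the edgeR count was 0 with total library size (569 genes at an unadjusted p under 0.05), with the stricter filter (501), with the 2 groups alone (481) and with the Gm42418 covariate (643). With an estimated correlation 4, 0 and 5 lists passed camera for age, IGF1 and IGF1-treated against young cells.

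With the Gm42418 covariate the age effect turned to 0.77 for Irs2 and 0.44 for histone genes. The IGF1 effect turned to 0.35 for Insr, −2.31 for Irs2, −0.0685 for Rpl6, −0.15 for oxidative phosphorylation genes, −0.15 for ribosomal protein genes, −0.0866 for MYC targets, 0.0013 for FOXO targets and −0.35 for histone genes. For IGF1-treated against young cells, histone genes had a median of 0.0538, with the direction of the test turned. Limma-voom turned Igf1r with age to −0.0261. The difference between the observed and simulated covariance of the age and IGF1 effects turned to −0.155 without a filter (share of simulations as far out 0.0099), −0.0108 with the replicate block (0.0297) and −0.0061 with limma-voom (0.257), against 0.0022 (0.673). With the controls split it was 0.0608, 0.0088 and 0.0346 with the age effect against control replicate 1, 2 or 3 alone and 0.0498, 0.0309 and 0.0285 with the IGF1 effect against them (shares 0.257 for the 0.0088 and 0.0099 for the others).

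With a library left out, the count of genes ran from 33 (young replicate 1) to 62 (middle-aged control replicate 1) for age, from 0 to 1 (middle-aged control replicate 3) for IGF1, and from 36 (young replicate 1) to 66 (IGF1 replicate 1) for IGF1-treated against young cells. Beside the IGF1 count of 0, 308 to 1092 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 2 with all libraries. The count of lists ran from 9 to 14, from 5 (IGF1 replicate 1) to 10 (IGF1 replicate 3) and from 13 to 17. The age effect of Igf1r ran from −0.0847 (young replicate 1) to 0.24 (young replicate 3) and that of Irs2 from −2.60 (young replicate 1) to 1.28 (young replicate 3). The IGF1 effect of Insr ran from −0.31 to 0.0409, and the medians of the HSC ageing list from −0.00726 to 0.15 and of oxidative phosphorylation genes from 0.0177 to 0.15. For IGF1-treated against young cells, Insr ran from −0.0164 to 0.41, Irs2 from −1.65 to 2.21 (young replicate 3) and NF-kB genes from −0.13 (IGF1 replicate 1) to 0.64. The covariance difference ran from −0.161 (middle-aged control replicate 1) to 0.0405 (replicate 2), with a share of 0.0099 without young replicate 1 or 2 or any control replicate and 0.0198 without IGF1 replicate 3.

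Groups share replicate numbers, but nothing in the labels says that a number marks a shared pool or day. Across genes, which are not independent replicates, deviations of same-numbered libraries correlated at 0.189, 0.0543 and 0.199 between the middle-aged groups, each library best with its own number. In the other comparisons the correlations ran from −0.125 to 0.137. Middle-aged control and IGF1 libraries of the same number may thus share a pool or day, which stays open. The main fit took the samples as unpaired, and the replicate block is the alternative that allows for a pairing. With the replicate block edgeR called 84, 1 and 94 genes, the effect on Irs2 of IGF1-treated against young cells turned to 0.0027, and the calls of Gbp4 (adjusted p = 0.0518) and Scd1 (0.0608) with age and of the endothelial and stromal list against young cells (0.0565) were no longer past the threshold.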

Other observations

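The tests of the Rpl27 copies, of the ribosomal protein shift, of the return of ageing genes and of the separate pairs of lists under the covariate were chosen after the result was seen, as were the MHC class II genes and the genes at 0 counts described here; the other tests were not.

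Of 10 genes of MHC class II antigen presentation looked at, 3 passed in at least 1 comparison; they were not followed through the alternative settings. H2-Eb1 had 3.42 ± 1.95 CPM in young control, 17.4 ± 8.81 CPM in middle-aged control and 21.0 ± 7.65 CPM in middle-aged IGF1 libraries (SD, n = 3 each), and passed in edgeR with age (adjusted p = 0.0345) and for IGF1-treated against young cells (0.0144). H2-Aa rose from 11.9 ± 4.81 to 45.3 ± 13.2 CPM and the invariant chain gene Cd74 from 35.2 ± 8.72 to 101 ± 23.0 CPM in IGF1-treated against young cells (adjusted p = 0.0103 and 0.0137 in edgeR), while with age alone neither passed (0.0761 and 0.353). H2-Ab1 and H2-DMa passed in no comparison. Some members went the other way without passing: H2-Ob had a log2 fold change of −1.91 (SE 0.71) with age, and H2-Oa −1.71 (SE 0.91) with IGF1. None of the 10 passed for IGF1 against vehicle in edgeR, where 500 of all genes had an unadjusted p under 0.05 and DESeq2 called 2 of all genes.

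Some genes had no count in any young library and passed in edgeR with age. Against a floor of 3 counts over the young group, Csn1s1 was at least 61.6-fold higher, Fndc10 60.2-fold, Chil5 34.5-fold, Rasef 29.1-fold, Eya4 26.1-fold and Sema4f 16.2-fold.

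With IGF1, 8 lists passed camera at the preset correlation and none with an estimated one (lowest adjusted p = 0.547). With the Gm42418 covariate 2 of 4 lists fell under 0.5 of their median. The histone and ribosomal protein medians turned to the opposite sign (larger ratio −0.583 of the value without the covariate). These lists were paired after their response was seen, so library composition that follows the ribosomal RNA signal stays open for them. NF-kB genes and mitochondrial mRNAs, also paired after their response was seen, kept at least 0.931 of theirs and both passed at the preset correlation. Their shifts thus remained in this fit, but a pair picked for that cannot exclude the Gm42418 signal. The mitochondrial ribosomal RNAs, which fell from 26.7% of counts in middle-aged control to 20.8% in IGF1 libraries, were not a covariate. The NF-kB shift also rested on IGF1 replicate 1, so differences in library composition stay open for both lists. For histones, genes whose RNA lacks a poly(A) tail had a median of 0.21 (SE 0.23, 21 genes), at percentile 81.54 of matched random lists. The 21 genes include Rn7s1 and Rn7s2, which hold the same values. The percentile lies under the bound set beforehand against more RNA without a poly(A) tail, but the SE spans the bound, a requirement added after the result was seen. Within groups, over the 9 libraries, the mean log2 level of these genes ran against Gm42418 (Pearson r = −0.70), while that of the histones ran with it (0.96). The explanation stays open by that requirement, and these correlations do not decide it. Ribosomal RNA, which Gm42418 covers, also counts as RNA without a poly(A) tail, but Gm42418 was left out of the 21 genes. The histones thus ran with such a signal and the 21 genes ran against it. An effect of IGF1 itself also stays open and was not tested apart from the groups.

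Rpl27-ps3 was lower with age and higher with IGF1. Reads moved between it and the other genes named Rpl27 or Rpl27-ps would leave their sum unchanged. The sum over these 4 genes was 262 ± 29.0, 164 ± 2.59 and 270 ± 58.9 CPM (SD, n = 3 each) in young, middle-aged control and IGF1 libraries, a change of at least 0.673 (log2) in both comparisons. Copies of Rpl27 under other names and reads assigned to no gene are outside this sum, so a move of reads to them was not tested. A shift of all ribosomal protein genes would move their median by a like amount, but their median was at most 0.0809 of its change. A difference between the pools at this gene was not tested, and no cause was found.

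Megakaryocyte and platelet genes and Col1a2 were higher with age. Platelets or megakaryocytes in the sort would raise abundant platelet transcripts, and the 5 tested had a median of 0.514, with Pf4 at 69.3 ± 12.7 and 98.8 ± 59.5 CPM (SD, n = 3 each) and Gp9 and Gp5 at −0.12 and −0.11, which does not decide between this and expression in LT-HSCs. Stromal cells would bring Col1a1 with Col1a2, but the highest ratio of their gains over the middle-aged control libraries was −0.00716. Age, the difference the design names, stays open and was not tested apart from these.

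A return of ageing genes towards the young level with IGF1 was tested as a hypothesis. The 39 genes of the ageing list had a median IGF1 log2 fold change of 0.0312, with 15 lower and 24 higher, above the bound of −0.2. The SE of this median, 0.046, is over genes, which are not independent replicates, so it cannot exclude a small return. Per library, the mean log2 CPM of the members, less its mean over the 9 libraries, was −1.17 ± 0.0888 in young control libraries. It was 0.557 ± 0.134 in middle-aged control and 0.614 ± 0.173 in IGF1 libraries (SD, n = 3 each). These values argue against a return of the list to the young level within 18 h, but not against a return near the size of the bound.

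Splits of 3 libraries against 3 are too few for a share under 0.05. For age, 1 of the 10 splits, the real one, gave as many as the 60 genes (highest other 13) and 1 as many as the 13 lists (highest other 8). For IGF1, 3 splits gave as many as the 1 gene (highest other 3) and 6 as many as the 8 lists (highest other 14). For IGF1-treated against young cells, 1 split gave as many as the 78 genes (highest other 1) and 3 as many as the 14 lists (highest other 15).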
